A study of Mus musculus with 10 samples.

How the data were processed

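Total RNA of inguinal subcutaneous white fat was sequenced in 10 libraries, 3 from sham mice, 4 after FLASH and 3 after CONV irradiation of the left hindlimb with 33.3 Gy, all sampled at day 70 and all given as sequencing batch 1. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, depleted of ribosomal RNA and made into stranded total RNA libraries, and the electrons came from an ElectronFlash linear accelerator. The files deposited by the authors hold raw counts, as whole numbers per gene symbol and library, without normalization. Per the submitters' processing notes, kallisto 0.5.0 and the mouse build mm10 were used. Each file ends in 5 entries for reads given to no gene, with the names that htseq-count writes, which fit counting of aligned reads rather than pseudoalignment. The aligner, the strand setting and the gene annotation are not given in the sources used here, so values of genes that overlap on opposite strands, and of close paralogs, are uncertain.

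The 10 files held 24421 gene symbols. Counts given to genes were 22.4 M to 36.0 M (M, 1e6) per library with a median of 31.2 M, and 17283 to 17969 genes had at least 1 count. All entries together summed to 67.9 M to 81.6 M per library, of which 52.0% to 69.6% fell in the entries for reads given to no gene. The largest of these, reads outside any annotated exon, held 44.2% to 62.9%, and ambiguous reads held 0.139% to 0.207%, unaligned reads 2.37% to 4.11% and reads aligned to several places 3.44% to 6.36%. The ribosomal precursor Rn45s took 1.79% to 8.39% of the gene counts. A count of 3, used as the floor for a gene not seen, equals 0.0833 to 0.134 CPM, which covers counting error only.

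The tests ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the group as design, which left 15266 genes with all 10 libraries, and libraries were scaled by TMM (factors 0.875 to 1.17). A quasi-likelihood negative binomial model with robust dispersion and 1 mean per group was fitted to all libraries together, and FLASH against sham, CONV against sham, FLASH against CONV and the mean of both irradiated groups against sham were tested as contrasts, two-sided. P-values were adjusted by Benjamini and Hochberg within each contrast, and a gene passed at an adjusted p under 0.05. The common biological coefficient of variation was 0.543 with all libraries and 0.284 without the lymphocyte-rich pair, where 15252 genes were tested.

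A total of 37 gene lists for cell types, metabolism, stress and radiation response were written before the data were examined, as were the contrasts, the test, the filter and most of the alternatives. The 36 lists with at least 3 measured members were tested by camera on limma voom values with a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera with a correlation estimated from the data and fry were run beside it. List means per library are averages of log2 CPM with a prior count of 2. Genes were named by a rule that was also set then. It takes up to 8 genes per direction among those past the threshold with mean log2 CPM of at least 2 and no overlap between groups, and the 3 members with the smallest p in the direction of each list past camera. It adds 14 genes of fat, damage and inflammation in every case, and, where fewer than 5 genes passed, the 5 with the smallest p in each direction, called not past the threshold. A few genes that the rule or the tests picked are not reported here. Gene locations came from GENCODE M21 on mm10, which holds 95.8% of the symbols.

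The agreement of the fold changes of FLASH and CONV was computed across genes from group means of CPM with 0.1 added, and compared with 50 simulations of unchanged groups with the same dispersions that shared the same sham libraries. Alternatives set at that time were DESeq2 size factors, upper-quartile factors and total counts as scaling, with no filter, 1 CPM in 3 libraries and a mean of 50 counts as filters. Others were DESeq2, limma voom and limma voom with quality weights as tests, a fit without robust dispersion, fits of only the 2 groups compared, the replicate number as a block, and leaving out each library. Libraries whose B cell list mean lay over 3 log2 units above the highest sham library were called lymphocyte-rich. Fits without these 2 libraries, with each of the 4 tools and with each further library left out, and a fit with the B cell list mean as a covariate, were added after the data were seen.

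The steps were tested on simulated data with the sizes, means and dispersions of these libraries and 100 genes changed by each fold. With all 10 libraries edgeR found 0% of 2-fold and 28%, 2% and 19% of 4-fold changes in FLASH against sham, CONV against sham and FLASH against CONV. Without the lymphocyte-rich pair it found 33%, 23% and 24% of 2-fold and 74%, 71% and 77% of 4-fold changes. Unchanged genes called in the same simulations numbered 8, 11 and 8 without the pair, and 2, 0 and 1 with all 10 libraries. Each value came from a single simulated draw. No library was left out of the tests with all 10 libraries, and the reads given to no gene were used only as shares.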

Results

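Gene expression was measured by total RNA sequencing in inguinal subcutaneous white fat of C57BL/6J mice, 70 days after the left hindlimb received 33.3 Gy of electrons. The dose was given either at ultra-high dose rate (FLASH, 4 libraries) or at conventional dose rate (CONV, 3 libraries), and 3 libraries came from mice that were not irradiated (sham). Counts assigned to genes were 34.9 M, 31.3 M and 28.9 M (M, 1e6) in sham replicates 1 to 3, 36.0 M, 28.6 M, 22.4 M and 32.0 M in FLASH replicates 1 to 4, and 31.5 M, 25.5 M and 31.1 M in CONV replicates 1 to 3. At these depths a count of 3 in a library equals 0.0833 to 0.134 CPM (counts scaled to 1e6 per library), and such floors cover counting error only. The sources used here do not say whether each library is a separate animal, so the p-values measure the spread between samples. Values per gene are CPM after TMM scaling with SD between libraries. Fold changes are log2 values from edgeR with their standard error (SE), in 15266 genes tested.

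FLASH replicate 3 and CONV replicate 2 held lymphocyte transcripts that the other 8 libraries had only at trace level. The follicular B cell and dendritic cell receptor gene Cr2 stood at 417 and 382 CPM in these libraries, against at most 0.544 CPM in each of the others, and Glycam1, made by the high endothelial venules of lymph nodes, at 36.9 and 144 CPM against 0 in all sham libraries. The mean of the B and plasma cell list lay 7.53 and 8.43 log2 units above the sham mean in these libraries, and 1.41 or less above it in the other 5 irradiated libraries. The mean of the adipocyte list lay at −2.29 and −2.76 in the same pair. Both libraries sat apart on the first principal component, which held 66.6% of the variance, with scores of 147 and 165 against −51.2 to −18.9 for the others. The choice of a second set of fits without this pair (FLASH n = 3, CONV n = 2, sham n = 3) was made after the data were seen. Results of this 8-library set stand beside those of all 10 libraries.

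**Figure D1:**
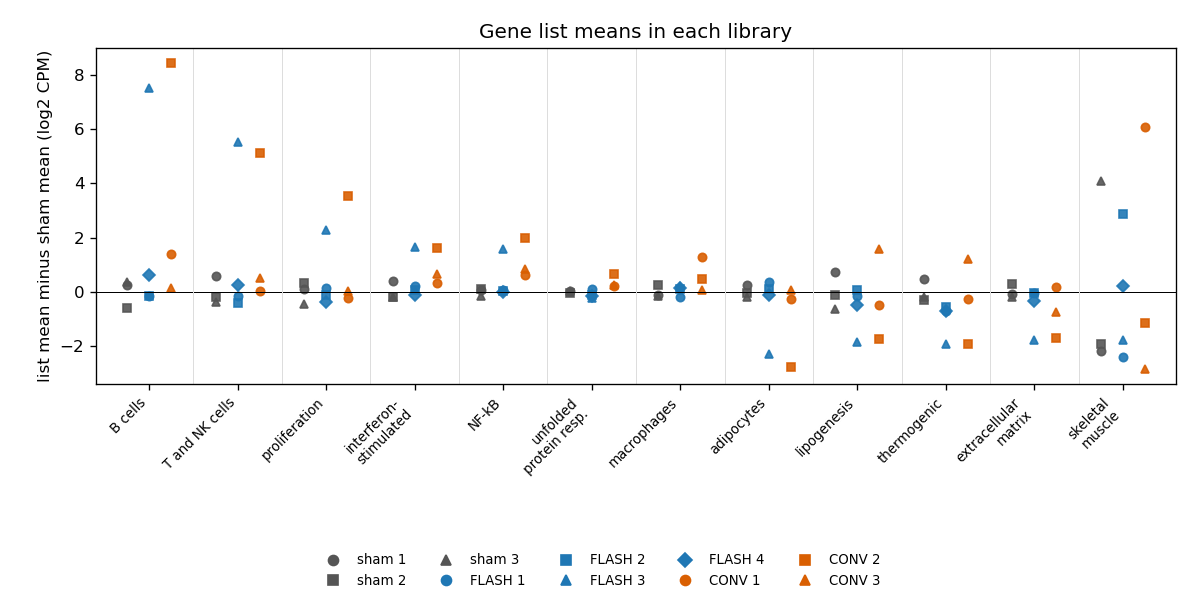
Mean log2 CPM of 12 gene lists in each library minus the sham mean, on a linear log2 axis, with 1 point per library, the colour giving the group and the marker the replicate. FLASH replicate 3 and CONV replicate 2 stand 7.53 and 8.43 log2 units above the sham mean for B cells.

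Other tissue content also differed between libraries of a group. Skeletal muscle genes lay 6.09 log2 units above the sham mean in CONV replicate 1 and 4.10 above it in sham replicate 3. In CONV replicate 3 they lay at −2.84. Keratinocyte and hair follicle genes lay 3.72 above it and mammary epithelial genes 3.21 above it in FLASH replicate 4. Red cell genes lay 3.74 above it in CONV replicate 1 and −1.38 from it in FLASH replicate 3. Genes of de novo lipogenesis lay 1.57 and brown and beige thermogenic genes 1.22 above it in CONV replicate 3, the library with the largest share of counts in its 10 most abundant genes (23.5%).

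FLASH and sham were compared to ask what the ultra-high dose rate left in the fat pad. No single gene passed. Among the genes with the smallest p was En1, a homeobox transcription factor of the dorsal and ventral body pattern, which stood at 2.05 ± 0.644 CPM (SD, n = 4) against 5.01 ± 0.787 CPM in sham (n = 3), a log2 fold change of −1.28 ± 0.31 (SE). Dkk2, a secreted Wnt modulator, had −1.52 ± 0.45, and Ldlrad4, a membrane protein that restrains TGF-beta signalling, −0.53 ± 0.16. Aknad1, a gene of little known function, had −1.91 ± 0.47 at 0.60 CPM in sham, and the HDL-bound esterase Pon1 had −1.81 ± 0.51. On the positive side stood Sphk1, which makes sphingosine 1-phosphate (1.48 ± 0.47), the heparan sulphate sulphotransferase Hs3st3b1 (1.48 ± 0.48), the monocyte chemokine Ccl8 (2.60 ± 0.87), the methyl-CpG binding protein Mbd1 (0.41 ± 0.13) and the adhesion receptor Adgrl1 (0.57 ± 0.19). Ccl8 stood at 40.0 CPM in FLASH replicate 3 and 6.40 ± 3.24 CPM in the other 3 FLASH libraries, and at 47.9, 15.6 and 25.2 CPM in CONV replicates 1 to 3.

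In edgeR 0 of 15266 genes passed in FLASH against sham, the lowest adjusted p being 0.998, and 99 had an unadjusted p under 0.05 where 763 would by chance. DESeq2, limma voom and limma voom with quality weights also called 0. With the 8 libraries edgeR called 0 with 385 at an unadjusted p under 0.05 (lowest adjusted p 1.00). DESeq2 called 4 there, named after their values were seen, with the microtubule protein Mapt and the long RNA C130026I21Rik lower and the transporters Slc35g1 and Slc5a3 higher. Both forms of limma voom called 0. The libraries of FLASH and sham did not overlap in 750 genes (4.91%), where chance gives 5.71%. Data simulated with the spread of these libraries gave 28% of 4-fold and 0% of 2-fold changes back with all 10 libraries. The shares were 74% and 33% without the pair. Changes of 2-fold were thus not detectable with all 10 libraries.

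Among the 37 gene lists fixed before the data were examined, the thermogenic, matrix and nerve lists had the smallest p in FLASH against sham. All 16 thermogenic genes measured had negative fold changes (median −0.78), among them the lipid droplet protein Cidea (−1.96 ± 1.03), the mitochondrial coactivator Ppargc1a (−0.83 ± 0.47) and the cytochrome oxidase subunit Cox8b (−1.44 ± 0.85). The list fell by camera at its preset correlation (adjusted p = 3.12e-06), with adjusted p = 0.778 with an estimated correlation. Sham replicate 1 held 40.7 CPM of Cidea and 30.4 CPM of Cox8b, the latter at 6.22 and 7.53 CPM in the other sham libraries, and without it Cidea had −0.95, Cox8b −0.35 and the list adjusted p = 0.00179. Of 32 extracellular matrix genes 30 had negative fold changes (median −0.43, adjusted p = 3.23e-06, and adjusted p = 0.778 with an estimated correlation), among them the metalloproteinase inhibitor Timp1 (−1.06 ± 0.47) and the proteoglycan Bgn (−0.58 ± 0.37). Of 11 Schwann cell and nerve genes 9 had negative fold changes (median −0.69, adjusted p = 7.79e-06, and adjusted p = 0.345 with an estimated correlation). The list included the myelin gene Prx (−1.15 ± 0.53) and the Schwann cell cadherin Cdh19 (−0.97 ± 0.45). The nerve list mean was 0.63 in sham replicate 2, −0.47 and −0.16 in sham replicates 1 and 3 and −1.02 to −0.50 in FLASH. Without sham replicate 2 Prx had −0.34 and the list adjusted p = 0.0163. Of 30 interferon-stimulated genes 28 had positive fold changes (median 0.53, adjusted p = 4.51e-05, and adjusted p = 0.778 with an estimated correlation), with the RNA sensor Oas2 at 0.87 ± 0.41. This list mean lay at 1.65 in FLASH replicate 3, and at −0.13 to 0.21 in the other 3 FLASH libraries, within the sham range of −0.21 to 0.39. Without the pair the list had a median of −0.02 (adjusted p = 0.374) and Oas2 had 0.42.

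Lower in FLASH by the same test were also lipogenesis (median −0.51, adjusted p = 0.000508), the tricarboxylic acid cycle (median −0.25, 0.00296), oxidative phosphorylation (median −0.17, 0.00540) and adipocyte genes (median −0.24, 0.00663). The same held for lipid-associated macrophage genes (median −0.22, 0.00717), fatty acid oxidation (median −0.26, 0.00844), adipose progenitors (median −0.41, 0.00844) and mural cells (median −0.31, 0.0110). Among the lipid-associated macrophage genes was Spp1, which encodes osteopontin (−1.80 ± 0.63). Higher were T and NK cell genes (median 4.30, adjusted p = 0.0104), with Ccr7 at 6.04 ± 2.80, Cd4 at 5.20 ± 2.45 and Lck at 4.83 ± 2.31. Ribosomal proteins were higher too (median 0.29, adjusted p = 0.0401). Each of these lists had adjusted p = 0.778 with an estimated correlation, and no list of any comparison passed that way in either set of libraries. In all, 14 of 36 lists passed in FLASH against sham, and over the 36 lists 0 members passed over all genes and 0 adjusted over the list alone. The number of lists was 2 without FLASH replicate 3, nerve and thermogenic genes, and 21 without FLASH replicate 4. With the 8 libraries 3 lists passed. List means of adipocyte genes ran from −0.10 to 0.36 in the 3 FLASH libraries kept, those of matrix genes from −0.36 to −0.06 and those of lipogenesis from −0.47 to 0.06, against −2.29, −1.80 and −1.86 in FLASH replicate 3. Nerve genes fell (11 of 11 negative, median −0.75, adjusted p = 6.52e-07, and adjusted p = 0.660 with an estimated correlation). Thermogenic genes fell (15 of 17 negative, median −0.64, adjusted p = 7.81e-05, and adjusted p = 0.815 with an estimated correlation). Ribosomal proteins, higher with all libraries, here fell (median −0.11, adjusted p = 0.00130, and adjusted p = 0.943 with an estimated correlation). The T cell genes Ccr7, Cd4 and Lck had log2 fold changes of 0.01, 0.19 and 0.27 there.

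CONV and sham were compared to ask what the conventional dose rate left in the same tissue. In the 8-library set 6 genes passed, 5 of them higher. Socs3, the feedback inhibitor induced by STAT3, stood at 44.5 ± 8.37 CPM in CONV (SD, n = 2) and 7.44 ± 0.302 CPM in sham (n = 3), and rose 5.90-fold (log2 fold change 2.56 ± 0.20 SE, edgeR adjusted p = 0.010). Card14, a scaffold of NF-kB signalling best known in keratinocytes, rose 9.07-fold (3.18 ± 0.24, adjusted p = 0.010), from 2.38 ± 0.374 to 21.9 ± 2.05 CPM. Prg4, the boundary lubricant lubricin, rose 7.07-fold (2.82 ± 0.26, adjusted p = 0.0228), and Il4ra, the receptor subunit shared by interleukin-4 and interleukin-13, rose 3.11-fold (1.64 ± 0.15, adjusted p = 0.0228). Vmp1, a membrane protein of autophagosome formation, rose 2.15-fold (1.10 ± 0.12, adjusted p = 0.0346). The values of these 5 genes in CONV lay outside those of sham in every library of that set, and they were named after their values were seen.

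With all 10 libraries the log2 fold changes were 2.67 ± 0.63 for Socs3, 2.64 ± 1.13 for Card14 and 2.31 ± 0.75 for Prg4. They were 1.85 ± 0.54 for Il4ra and 0.97 ± 0.18 for Vmp1, and all 5 genes had adjusted p = 0.607. Socs3, Il4ra and Vmp1 had no overlap between CONV and sham there, whereas Card14 (0.670 CPM) and Prg4 (1.41 CPM) were low in CONV replicate 2. In that lymphocyte-rich library Socs3 stood at 53.4 CPM and Il4ra at 184 CPM, and in lymphocyte-rich FLASH replicate 3 at 35.6 and 182 CPM. The other FLASH libraries held 6.11 to 8.96 CPM of Socs3 and 47.0 to 51.1 CPM of Il4ra. For these genes the values of CONV replicate 2 can thus not be told from lymphoid content. In GENCODE M21 on GRCm38 (mm10), Socs3 lies on chromosome 11 from 117966079 to 117970047, Card14 on chromosome 11 from 119307768 to 119345375 and Prg4 on chromosome 1 from 150449412 to 150466165. Il4ra lies on chromosome 7 from 125552120 to 125579474 and Vmp1 on chromosome 11 from 86583865 to 86683836. Exons of Card14 overlap Sgsh and exons of Prg4 overlap Tpr on the opposite strand, and the strand used for counting is not given in the sources used here. Sgsh (25.8, 34.7 and 33.1 CPM in sham, FLASH and CONV) and Tpr (225, 218 and 219 CPM) did not follow them. Vmp1 shares an exon with the microRNA gene Mir21a, which had a count of 0 in all libraries. Reads in that exon lie in both genes and may have been set aside as ambiguous, so this count says nothing on Mir21a.

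**Figure D2:**
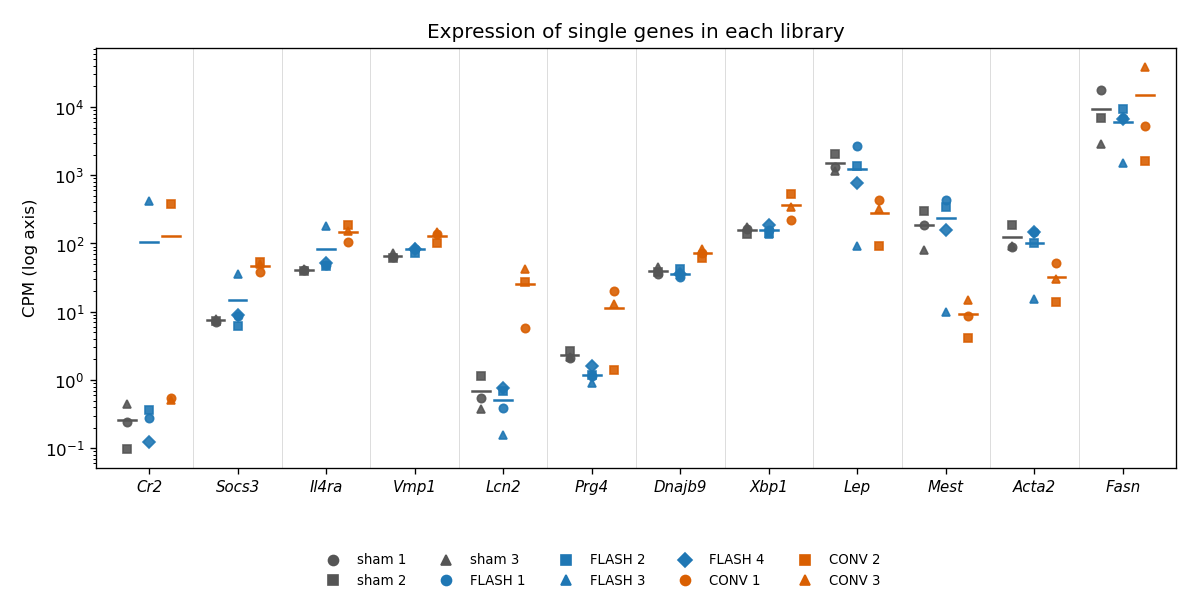
CPM of 12 genes in each library on a log axis, by group, with a bar at each group mean and 1 point per library. Socs3 lies between 38.6 and 53.4 CPM in the 3 CONV libraries and between 7.17 and 7.77 CPM in the 3 sham libraries. The highest CONV value is that of lymphocyte-rich CONV replicate 2, and lymphocyte-rich FLASH replicate 3 holds 35.6 CPM.

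In edgeR 0 genes passed in CONV against sham with all 10 libraries (lowest adjusted p 0.607), while 889 had an unadjusted p under 0.05 where 763 would by chance. DESeq2 called 66 (49 higher, 17 lower), limma voom 0 and limma voom with quality weights 1, which was Socs3 (2.55, adjusted p = 0.0244). EdgeR called Socs3 alone (adjusted p = 0.0166) when only FLASH replicate 3 was left out, a fit that kept the lymphocyte-rich CONV replicate 2. Among the genes with the smallest p in all 10 libraries were Lcn2, an acute-phase siderophore-binding protein (5.19 ± 0.90), Fkbp5, a glucocorticoid-induced chaperone (1.34 ± 0.23), the elastic fibre protein Emilin1 (1.25 ± 0.22) and the oligoadenylate synthase Oas1g (1.75 ± 0.34). On the negative side stood Ldlrad4 (−0.89 ± 0.17), the RNA editing family member Adarb2 (−3.96 ± 0.86) and Ankrd29 (−2.62 ± 0.58). The microRNA gene Mir335 (−5.25 ± 1.04) lies inside Mest. Adarb2 and Mir335 had CONV means of 0.0891 and 0.0570 CPM, near the floor, so the sizes of their fold changes are uncertain. Without the pair edgeR called 6 (5 higher, 1 lower) with 2022 at an unadjusted p under 0.05, DESeq2 661, limma voom 4 and limma voom with quality weights 4, in both cases Socs3, Card14, Prg4 and Il4ra. All 6 of the edgeR calls were among those of DESeq2. The count depended on single libraries of this smaller set. It was 0 without any 1 of the 3 sham libraries, 2 without FLASH replicate 2, 1134 without CONV replicate 1 and 138 without CONV replicate 3, where a single CONV library is assumed to vary like the other groups. The 6 calls kept their sign in all 8 of these fits, and an unadjusted p under 0.05 in edgeR in those with both CONV libraries. As they were picked for the smallest p in the same libraries, this was close to fixed in advance. The groups did not overlap in 2701 genes (17.7%, chance 10%) with all libraries and in 3982 (26.1%, chance 20%) without the pair.

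Inflammatory and secretory stress lists were higher in CONV than in sham. Of 16 unfolded protein response genes 13 had positive fold changes (median 0.46, camera adjusted p = 0.00131, and adjusted p = 0.955 with an estimated correlation), among them the transcription factors Xbp1 (1.23 ± 0.31) and Atf4 (0.45 ± 0.16). The ER chaperone Dnajb9 stood at 71.9 ± 10.6 CPM against 39.8 ± 5.05 in sham (0.85 ± 0.18). Of 19 NF-kB and acute inflammation genes 17 were positive (median 1.34, adjusted p = 0.00230, and adjusted p = 0.955 with an estimated correlation), with Lcn2, the acute-phase protein Saa3 (4.89 ± 1.32) and the cytokine Il1b (4.54 ± 1.34). Of 19 macrophage genes 18 were positive (median 0.75, adjusted p = 0.000394, and adjusted p = 0.955 with an estimated correlation), with the Fc receptor Fcgr1 at 1.54 ± 0.36, the integrin Itgam at 0.75 ± 0.28 and the lysozyme Lyz2 at 1.5 ± 0.64. The macrophage mean lay 1.28 above sham in CONV replicate 1 and 0.06 above it in CONV replicate 3, and the list had adjusted p = 0.353 without CONV replicate 1. Saa3 had 2.16 without CONV replicate 3. Of 30 interferon-stimulated genes 28 were positive (median 1.02, adjusted p = 3.77e-06, and adjusted p = 0.955 with an estimated correlation), with Oas2 at 1.87 ± 0.44, Oasl2 at 1.04 ± 0.29 and Oas1a at 1.58 ± 0.51. This list mean lay at 1.61 in CONV replicate 2 and 0.66 in CONV replicate 3, and at 0.33 in CONV replicate 1, within the sham range. Without the pair the list median was 0.44. Oas1a and Oas1g are close paralogs, so reads may have been shared between them.

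Vessel wall, nerve and adipocyte lists were lower in CONV than in sham, each with adjusted p = 0.955 with an estimated correlation. Of 12 mural cell genes 10 were negative (median −0.67, adjusted p = 0.00199), with the pericyte gene Rgs5 at −1.14 ± 0.42 and smooth muscle actin Acta2 at −1.94 ± 0.78. The same direction was found for adipocyte genes (20 of 24, median −0.49, adjusted p = 0.00139), with the leptin gene Lep at −2.39 ± 1.01 and the natriuretic clearance receptor Npr3 at −2.28 ± 1.16. So it was for extracellular matrix genes (28 of 32, median −0.54, adjusted p = 0.000337), with Sparc at −1.24 ± 0.80. It was also found for endothelial genes (14 of 17, median −0.29, adjusted p = 0.0134), with the VEGF receptor Kdr at −0.52 ± 0.25, and nerve genes (9 of 11, median −0.73, adjusted p = 0.0135), with S100b at −1.90 ± 0.82. Progenitors (12 of 17, median −0.64, adjusted p = 0.0148) were lower too, as were lipolysis genes (12 of 18, median −0.39, adjusted p = 0.0237). The lower adipocyte, lipolysis and endothelial values came from CONV replicate 2, whose list means were −2.76, −2.17 and −1.37. In CONV replicates 1 and 3 these were −0.28 and 0.07 for adipocytes, −0.18 and 0.42 for lipolysis and −0.11 and 0.16 for endothelium. Without the pair their medians were −0.04, 0.06 and −0.07 (adjusted p = 0.568, 0.681 and 0.963). Without sham replicate 2 nerve genes had adjusted p = 0.224 and progenitors 0.0675, and without CONV replicate 2 matrix genes had 0.0885. Higher, again with adjusted p = 0.955 with an estimated correlation, were ribosomal proteins (25 of 25, median 0.67, adjusted p = 0.000337) and proliferation genes (25 of 25, median 2.23, adjusted p = 0.000794). The same was found for T and NK cell genes (17 of 17, median 4.02, adjusted p = 0.00702) and B and plasma cell genes (13 of 13, median 7.91, adjusted p = 0.0135), with Mzb1 at 10.56 ± 3.86 and Ms4a1 at 8.28 ± 3.69. The proliferation mean was 3.55 in CONV replicate 2 and −0.24 and 0.04 in CONV replicates 1 and 3, and the ribosomal mean was 1.42 against −0.13 and 0.23. None of these 4 lists passed without CONV replicate 2 (adjusted p = 0.622 for proliferation and 0.826 for ribosomal proteins).

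In all, 15 of 36 lists passed in CONV against sham, ranging from 13 without sham replicate 2 to 23 without CONV replicate 3, and over the 36 lists 0 members passed over all genes and 10 adjusted over the list alone. With the 8 libraries 12 lists passed. Over the 36 lists there, 2 memberships passed over all genes, both of Socs3, in the insulin and immediate early lists, and 52 adjusted over the list alone. B cell, T cell and proliferation genes were not among the 12 lists. These were, in order, macrophages (19 of 19 positive, median 0.70, adjusted p = 4.8e-05), interferon-stimulated genes (median 0.44, 5.52e-05), oxidative phosphorylation (32 of 32 positive, median 0.45, 8.19e-05) and red cell genes (median 3.13, 0.000198), all higher. Also higher were the tricarboxylic acid cycle (median 0.36, 0.00277), the unfolded protein response (median 0.24, 0.00277), fatty acid oxidation (median 0.39, 0.00360), NF-kB genes (median 0.31, 0.00360) and lipogenesis (median 0.90, 0.00759). The 4 metabolic lists were high in CONV replicate 3 alone, with means of 0.96 for oxidative phosphorylation, 0.81 for the tricarboxylic acid cycle, 0.85 for fatty acid oxidation and 1.57 for lipogenesis. In CONV replicate 1 they lay at −0.15, −0.12, −0.07 and −0.48. Mural (median −0.52, 0.0215), nerve (median −0.66, 0.0398) and matrix genes (median −0.29, 0.0420) were lower. With an estimated correlation adjusted p = 0.477 for the unfolded protein response and NF-kB lists and 0.843 for the others. By fry, which tests whether the members move one way on balance and not against other genes, NF-kB (adjusted p = 0.000213) and unfolded protein response genes (adjusted p = 0.0347) passed in that set.

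FLASH was compared directly with CONV to ask whether the dose rate at the same dose made a difference. In the 8-library set 2 genes passed, both lower in FLASH. Prg4 fell 12.5-fold (−3.65 ± 0.27, edgeR adjusted p = 0.0126), with 1.30 ± 0.240 CPM in FLASH (SD, n = 3) and 16.4 ± 4.93 CPM in CONV (n = 2). Socs3 fell 5.57-fold (−2.48 ± 0.20, edgeR adjusted p = 0.0126), with 7.91 ± 1.57 against 44.5 ± 8.37 CPM. With all 10 libraries their values were −3.25 ± 0.70 and −1.68 ± 0.55 (adjusted p = 0.999 each), with Prg4 at 1.41 CPM in CONV replicate 2 and Socs3 at 35.6 CPM in FLASH replicate 3. The smallest p among all 10 libraries belonged to Lcn2 (−5.62 ± 0.81), at 0.504 ± 0.285 CPM in FLASH and 25.1 ± 18.6 in CONV, and to Dnajb9 (−1.0 ± 0.17). The coagulation factor gene F10 (−2.96 ± 0.59), the stem cell antigen Ly6a (−0.86 ± 0.17) and the matrix protein Spon1 (−1.19 ± 0.24) followed in that direction. Mir335 (5.55 ± 1.03), Slc22a14 (3.10 ± 0.65), the secreted phospholipase Pla2g5 (2.77 ± 0.57), D430019H16Rik (2.99 ± 0.71) and Adarb2 (3.42 ± 0.83) lay in the other, none past the threshold. Mir335, Slc22a14 and Adarb2 had CONV means of 0.0570, 0.0805 and 0.0891 CPM, near the floor. The sizes of these 3 fold changes are thus uncertain.

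In edgeR 0 genes passed in FLASH against CONV with all 10 libraries (lowest adjusted p 0.999), with 453 at an unadjusted p under 0.05. DESeq2 called 40 (18 higher, 22 lower), limma voom 0 and limma voom with quality weights 1, which was Socs3 (−2.56, adjusted p = 0.0227). EdgeR called Socs3 alone (adjusted p = 0.0207) when only FLASH replicate 3 was left out, and Prg4 alone (adjusted p = 0.0210) when only CONV replicate 2 was left out. The former fit kept the lymphocyte-rich CONV replicate 2, so lymphoid content then differed between the groups. Without the pair edgeR called 2 with 2082 at an unadjusted p under 0.05, DESeq2 667, limma voom 3 (Card14, Prg4 and Socs3) and limma voom with quality weights 2 (Prg4 and Socs3). In that set the count was 0 without any 1 of sham replicates 1 and 3 or FLASH replicates 1, 2 and 4, 3 without sham replicate 2, 1025 without CONV replicate 1 and 86 without CONV replicate 3. No overlap was seen in 344 genes (2.25%, chance 5.71%) with all libraries and in 3979 (26.1%, chance 20%) without the pair.

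With all 10 libraries the unfolded protein response was the list with the smallest p in FLASH against CONV. Of its 16 genes 13 were lower in FLASH (median −0.64, camera adjusted p = 4.58e-09, and adjusted p = 0.0760 with an estimated correlation), with Dnajb9, Xbp1 (−1.23 ± 0.28) and the lectin chaperone Calr (−0.72 ± 0.17). It was also the 1 list that passed by fry with all libraries (adjusted p = 0.0424), and 8 of its members passed adjusted over the list alone, 7 of them lower. The plasma cell gene Mzb1 stood at 209 CPM in CONV replicate 2, where the list mean was 0.65 against 0.22 and 0.24 in CONV replicates 1 and 3, and Xbp1 stood at 539 CPM there against 221 and 341. Without the pair Xbp1 had −0.78 ± 0.21. Macrophage genes were lower as well (18 of 19, median −0.64, adjusted p = 3.31e-06), with Fcgr1 at −1.43 ± 0.33, Itgam at −0.83 ± 0.26 and Cd68 at −0.78 ± 0.31. So were interferon-stimulated genes (21 of 30, median −0.30, adjusted p = 0.000524), with Oas2 at −1.0 ± 0.40 and Oasl2 at −0.61 ± 0.26, and red cell genes (5 of 5, median −2.41, adjusted p = 0.00651), with Slc4a1 at −2.82 ± 0.99. NF-kB genes were lower (14 of 19, median −0.17, adjusted p = 0.00860), with Saa3 at −4.94 ± 1.17. Lipogenesis was lower (22 of 24, median −1.03, adjusted p = 0.0312), with Acacb at −1.77 ± 0.75, Acly at −2.03 ± 1.00 and Elovl6 at −2.30 ± 1.20. Without CONV replicate 3 these had −0.36, 0.40 and 0.93 and Saa3 had −2.21. Macrophage and red cell genes did not pass without CONV replicate 1 (adjusted p = 0.274 and 0.748) or interferon and NF-kB genes without CONV replicate 2 (0.718 and 0.189), whereas the unfolded protein response passed with any 1 library left out. Each of these from macrophages on had adjusted p = 0.90 with an estimated correlation.

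Also lower in FLASH were ribosomal proteins (median −0.38, adjusted p = 0.00112), proliferation (median −1.36, 0.00285), oxidative phosphorylation (median −0.37, 0.00595), glycolysis (median −0.48, 0.0378) and B cell genes (median −0.79, 0.0384). The proliferation mean was 3.55 in CONV replicate 2, 2.30 in FLASH replicate 3 and −0.38 to 0.14 in the other 5 irradiated libraries, and without the pair the list had a median of 0.05 (adjusted p = 0.935). The ribosomal mean was 1.42 in CONV replicate 2, 1.03 in FLASH replicate 3 and −0.25 to 0.23 in the others. Higher were mural (median 0.39, adjusted p = 0.0312), adipocyte (median 0.38, 0.0384) and endothelial genes (median 0.13, 0.0487), with Acta2 at 1.67 ± 0.74, Rgs5 at 0.78 ± 0.39 and Npr3 at 2.35 ± 1.12. All had adjusted p = 0.90 with an estimated correlation. The 14 lists past the test became 8 without FLASH replicate 4 and 25 without CONV replicate 3, and over the 36 lists 0 members passed over all genes and 13 adjusted over the list alone. Without the pair 11 lists passed, all lower in FLASH, and over the 36 lists 2 memberships passed over all genes, both of Socs3, and 60 adjusted over the list alone. The 11 lists were oxidative phosphorylation, interferon and macrophage genes (adjusted p = 0.000121 each), the unfolded protein response (0.000125), red cells (0.000463), the tricarboxylic acid cycle (0.000709), lipogenesis and fatty acid oxidation (0.00201 each), NF-kB (0.00256), thermogenic genes (median −1.64, 0.00546) and ribosomal proteins (0.0167). The thermogenic mean was 1.22 in CONV replicate 3 and −0.27 in CONV replicate 1, and the 4 metabolic lists higher in CONV than in sham here were high in CONV replicate 3 alone. With an estimated correlation adjusted p = 0.246 for the unfolded protein response and NF-kB and 0.855 for the rest. By fry the unfolded protein response (adjusted p = 0.0113) and NF-kB (adjusted p = 3.0e-05) passed in that set.

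The mean of both irradiated groups was compared with sham to ask what the dose left whatever its rate. Ldlrad4 stood at 22.7 ± 2.56 CPM in FLASH and 17.7 ± 1.81 in CONV against 32.8 ± 3.24 in sham, a log2 fold change of −0.71 ± 0.14 (edgeR adjusted p = 0.750). En1 (−1.32 ± 0.27), Aknad1 (−2.01 ± 0.40), the Hedgehog transcription factor Gli2 (−1.14 ± 0.27) and Dkk2 (−1.59 ± 0.39) were on the same side. Fkbp5 (0.97 ± 0.20), Vmp1 (0.65 ± 0.16), Emilin1 (0.79 ± 0.19), Oas1g (1.19 ± 0.30) and Hs3st3b1 (1.81 ± 0.46) were on the other. In edgeR 0 genes passed (lowest adjusted p 0.750), with 458 at an unadjusted p under 0.05. DESeq2 called 8 (6 higher, 2 lower) and both forms of limma voom 0. Without the pair edgeR called 0 with 1050 at an unadjusted p under 0.05 (lowest adjusted p 0.141), DESeq2 129 and both forms of limma voom 0. EdgeR called 39 when CONV replicate 1 was left out as well. No overlap was seen in 277 genes (1.81%, chance 1.67%) with all libraries and in 489 (3.21%, chance 3.57%) without the pair.

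By list, interferon-stimulated genes were the most separated in the irradiated groups (28 of 30 positive, median 0.73, adjusted p = 3.21e-06), with Oas2 at 1.37 ± 0.39. The list mean was 1.65 in FLASH replicate 3 and 1.61 in CONV replicate 2, and 0.66 or less in the other 5 irradiated libraries. Nerve genes were lower (9 of 11, median −0.68, adjusted p = 0.00108), with Prx at −1.13 ± 0.46 and S100b at −1.50 ± 0.64. Lower too were matrix (median −0.51, adjusted p = 3.32e-05), adipocyte (median −0.36, 0.00292) and mural genes (median −0.45, 0.00292), with Rgs5 at −0.75 ± 0.34, and thermogenic genes (median −0.38, 0.00389). So were progenitor (median −0.46, 0.00901), endothelial (median −0.29, 0.0208) and lipolysis genes (median −0.24, 0.0280). Higher were ribosomal proteins (median 0.48, adjusted p = 0.00111), proliferation (median 1.58, 0.00307), T and NK cells (median 4.14, 0.00703), NF-kB (median 1.26, 0.00737), with Il1b at 3.77 ± 1.23, macrophages (median 0.42, 0.00737) and B cells (median 7.54, 0.0260). Proliferation means were 2.30 in FLASH replicate 3, 3.55 in CONV replicate 2 and 0.14 or less in the other 5 irradiated libraries, and ribosomal means 1.03, 1.42 and 0.23 or less. Without the pair neither list passed (adjusted p = 0.163 and 0.221). Without sham replicate 2 nerve genes had adjusted p = 0.0577 and Prx had −0.32, and without CONV replicate 1 macrophages had adjusted p = 0.386. Each of the 15 lists had adjusted p = 0.888 with an estimated correlation, and over the 36 lists 0 members passed over all genes and 0 adjusted over the list alone. The number of lists was 8 without CONV replicate 2 and 21 without CONV replicate 3. Without the pair 6 lists passed, namely interferon (median 0.19, adjusted p = 0.000359), nerve (11 of 11 negative, median −0.61, 0.000359), macrophage (median 0.38, 0.000699), oxidative phosphorylation (median 0.23, 0.00300), red cell (median 1.88, 0.00300) and matrix genes (median −0.20, 0.0497). Each had adjusted p = 0.803 with an estimated correlation, over the 36 lists 18 members passed adjusted over the list alone and 0 over all genes, and NF-kB passed by fry (adjusted p = 0.0110).

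Genes of DNA damage, senescence and fat identity that were always reported did not pass in any comparison. Against sham the p53 targets Cdkn1a and Ccng1 had log2 fold changes of 0.33 and −0.11 in FLASH and −0.64 and −0.05 in CONV, and the stress cytokine Gdf15 had 0.94 ± 0.63 and 1.67 ± 0.65 at 0.118 ± 0.0681 CPM in sham, close to the floor. The adiponectin gene Adipoq had −0.38 in FLASH and −0.78 in CONV, Pparg −0.36 and −0.42, Lep −0.28 and −2.39, Fasn −0.59 and 0.71 and Scd1 −0.14 and −0.13. The collagens Col1a1 and Col3a1 had −0.55 and −0.57 in FLASH and −0.43 and −0.37 in CONV, the chemokine Ccl2 −0.46 and 0.09, and the macrophage gene Cd68 −0.03 and 0.76. Ucp1 and Cdkn2a did not pass the filter with all 10 libraries. Without the pair Ucp1 was tested, with −4.56 ± 2.56 in FLASH and 2.89 ± 2.00 in CONV against sham and −7.46 ± 2.67 in FLASH against CONV (adjusted p = 0.281), and its counts lay mostly in CONV replicate 3 (561) and sham replicate 1 (130). Ucp1 stood at 1.35 ± 2.25 CPM in sham, 0.0690 ± 0.0605 in FLASH and 6.92 ± 11.9 in CONV, and Cdkn2a at 0.0969 ± 0.0571, 0.331 ± 0.476 and 0.492 ± 0.678 CPM.

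Lists that passed in none of the 4 comparisons with all libraries had adjusted p = 0.668, 0.771, 0.865 and 0.741 for p53 targets, in the order FLASH against sham, CONV against sham, FLASH against CONV and irradiated against sham. In this order they were 0.689, 0.826, 0.865 and 0.865 for senescence, 0.586, 0.210, 0.190 and 0.241 for TGF-beta signalling, and 0.152, 0.0578, 0.190 and 0.0671 for DNA break repair. Insulin signalling had 0.918, 0.569, 0.428 and 0.746, antioxidant genes 0.184, 0.445, 0.865 and 0.300, the circadian clock 0.0600, 0.424, 0.865 and 0.184, and immediate early genes of tissue handling 0.144, 0.866, 0.276 and 0.579. Granulocytes had 0.410, 0.826, 0.646 and 0.640, lymphatic endothelium 0.684, 0.689, 0.305 and 0.889, skeletal muscle 0.601, 0.689, 0.265 and 0.952, mammary epithelium 0.817, 0.689, 0.710 and 0.813, and keratinocytes 0.567, 0.968, 0.595 and 0.865. The mitochondrially encoded list had 0 members in the files. In CONV against sham the list median and the camera direction differed in sign for thermogenic, tricarboxylic acid cycle, lipogenesis, granulocyte and keratinocyte genes, each with a positive median and a negative direction. They also differed for red cell genes in FLASH against sham, antioxidant and mammary genes in FLASH against CONV, and oxidative phosphorylation, insulin and lymphatic genes in irradiated against sham. The mean alone differed in sign from the test for fatty acid oxidation in CONV against sham, for immediate early genes in each comparison with sham, and for T and NK cell and senescence genes in FLASH against CONV. It also did for antioxidant genes in each comparison with sham, for glycolysis, TGF-beta, granulocyte and lymphatic genes in FLASH against sham, and for granulocyte genes in irradiated against sham.

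Fold changes against sham were correlated between FLASH and CONV across genes, which are not independent replicates, with Pearson r = 0.814, Spearman rho = 0.726 and a covariance of 0.590, and 79.5% of genes had the same sign. Unchanged groups simulated with the same 3 shared sham libraries gave r = 0.534 (0.507 to 0.561), a covariance of 0.219 and 68.0% of the same sign. The excess covariance of 0.371 is thus what was left after the sharing of sham libraries as simulated. Sham could not be split into separate controls, so whether the simulation removed the whole effect of sharing was not checked. In the 8-library set r was 0.195 and the covariance 0.0405, below the simulated 0.443 and 0.0761, so no excess of covariance was left without the pair (difference −0.0356). With all but 1 library, r was 0.125 without FLASH replicate 3 and 0.258 without CONV replicate 2. These sets were not simulated, so their r has no value for unchanged groups beside it.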

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

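The tests for lymph node tissue, for a lymphocyte rise in all irradiated libraries, for muscle and macrophages in CONV replicates 1 and 3 and for fewer adipocytes were chosen only after the result was seen, while the tests on other splits were set before.

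In groups of 4 libraries, which only FLASH offered, each list mean and each gene named was checked for a library far from the others, in 117 groups. Chance flags about 1 in 20 groups, and 19 stood apart, 18 of them through FLASH replicate 3. Its list means relative to sham were 7.53 for B and plasma cells (nearest other library 0.62), 5.53 for T and NK cells (0.25), 1.57 for NF-kB (0.07), 1.02 for DNA break repair (−0.03), −0.66 for insulin signalling (0.04) and −1.91 for thermogenic genes (−0.72). Lymphocyte genes stood far above the nearest library, with Ms4a1 at 271 CPM, Cd4 at 157 CPM, Lck at 135 CPM, Ccr7 at 62.3 CPM and Mzb1 at 29.1 CPM. Genes that lymph nodes share with other tissue stood high as well, with Il4ra at 182 CPM, Socs3 at 35.6 CPM, Lyz2 at 781 CPM, Cd68 at 29.1 CPM, Il1b at 4.63 CPM and Cdkn2a at 1.04 CPM, whereas the lipogenic desaturase Scd1 was low at 15227 CPM against 62714 CPM in the nearest library. Apart from this library, the transporter gene Slc22a14 stood at 1.27 CPM in FLASH replicate 1 against 0.579 CPM in the nearest. Reads outside any annotated exon, which the comparisons did not use, made up 62.9% in FLASH replicate 3, 58.9% in CONV replicate 2 and 54.5% in CONV replicate 1, above the 53.8% of the highest sham library.

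The lymphocyte transcripts of FLASH replicate 3 and CONV replicate 2 were weighed first. Of 12 genes of lymph node vessels, stroma and follicles, 10 stood over 3 log2 units above the highest of the other 8 libraries in both, with Fcer2a at 282 and 279 CPM, while Ccl19 had 0 counts everywhere and Madcam1 missed the margin. A lymphocyte rise in all irradiated fat is argued against, since the median B cell list mean of the other 5 irradiated libraries was 0.130 above sham. Lymph node tissue taken with the fat pad is a candidate source, and lymphoid tissue grown within the fat of single mice was not tested.

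The second pattern was the set of genes higher in CONV replicates 1 and 3 than in sham, such as Socs3, Card14 and Prg4. A trace of lymph node could give 0% of the rise of any called gene in CONV replicate 3 and at most 2.58% in CONV replicate 1. Skeletal muscle is argued against in CONV replicate 3 by the muscle list mean, which at −2.84 lay below the lowest sham library (−2.19). More macrophages are argued against there by the macrophage list mean of 0.0563, below the highest sham library (0.267). Blood in the sample was not tested and stays open, as red cell genes lay 3.74 above the sham mean in CONV replicate 1 and 1.37 above it in CONV replicate 3, with sham libraries at −0.10 to 0.08. CONV irradiation itself and a difference between samples of any other kind stay open too, since CONV had 2 libraries in this set.

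The third pattern was the lower Lep, Mest and Peg3 in CONV, noticed without the pair. There Lep had −1.99 ± 0.52, Mest −4.03 ± 0.69 and Peg3 −2.31 ± 0.37, with adjusted p of 0.170, 0.0924 and 0.0854, so none passed. Fewer adipocytes in the sample are argued against, as the other 23 adipocyte genes had a median log2 fold change of 0.01 (0.00571). Exons of Mest overlap Copg2 on the opposite strand, which stood at 64.8, 61.8 and 48.4 CPM in sham, FLASH and CONV.

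Other ways to split the same libraries were run for each count of genes. With all libraries the real split called 0 genes in each comparison, so every split gives as many and these counts decide nothing on chance. They were 35 of 35 splits for FLASH against sham, 10 of 10 for CONV against sham, 35 of 35 for FLASH against CONV and 100 of 100 drawn splits for irradiated against sham. The highest other split called 0, 0, 4548 and 6235 genes in this order. Over 1000 genes were called in 6 drawn splits of irradiated and sham libraries, which were all 6 that put both lymphocyte-rich libraries in the group of 3, and this points to a structure of the samples. In FLASH against CONV only 2 of the 15 splits that kept both in one group called over 1000 genes. Without the pair there are 10 splits, too few for a share under 0.05. There the real split of CONV and sham called 6 and the highest other 2. The real split of FLASH and CONV called 2 and the highest other 0, with 1 split as large in each, the real one. By genes at an unadjusted p under 0.05 in edgeR the real splits were not the largest. For CONV and sham the real split had 2022, and sham replicate 1 grouped with CONV replicate 3 had 3777. For FLASH and CONV the real split had 2082, and FLASH replicates 2 and 4 grouped with CONV replicate 1 had 2419. With all libraries the real split of CONV and sham had 889, and sham replicate 1 grouped with CONV replicates 2 and 3 had 1719.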

How the results depend on the processing

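Tests with only 8 libraries, with the B cell covariate, and of the agreement without each library were chosen after the data were seen, and the other alternatives were planned.

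Scaling, filters, the fit without robust dispersion and fits of only the 2 groups compared kept every edgeR count at 0, as did limma voom. DESeq2 called 66 genes in CONV against sham, 40 in FLASH against CONV and 8 in irradiated against sham, and limma voom with quality weights 1 in each of the first 2, Socs3 both times. The replicate block kept all gene counts at 0 and moved the lists of FLASH against sham to 22. Of 9 pairs of libraries that share a number 2 correlated above 0.1 (range −0.756 to 0.261). Of 10 libraries 0 correlated best with their own number, though FLASH replicate 4 had no partner of its number. The number is thus not read as a pairing. A pairing is not excluded, since FLASH replicate 3 and CONV replicate 2 correlated at 0.898 through their lymphocyte transcripts or other shared content. With an estimated correlation 0 lists passed in each comparison, and by fry 0, 0, 1 and 0. With 8 libraries 3 lists passed in FLASH against sham and 6 in irradiated against sham. EdgeR called 6 genes in CONV against sham and 2 in FLASH against CONV, DESeq2 4, 661, 667 and 129, limma voom 4 and 3, and limma voom with quality weights 4 and 2. The B cell covariate gave 1 gene in FLASH against CONV, the granulocyte receptor Csf3r, named after its values were seen. The agreement of fold changes was 0.195 without the pair. Leaving out the pair lowers the number of samples and removes the lymphocyte transcripts, and leaving out 1 library lowers the number of samples, and beyond this the cause was not tested. Across 134 fold changes of named genes, 85 of 3561 alternative values changed sign, 118 passed the threshold and 128 moved by over 1 SE. Depth limited genes near the floor such as Gdf15 and Ucp1.

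Sign changes of log2 fold changes, all of genes not past the threshold, had a cause that was not tested. Upper-quartile scaling gave 0.00193 for Scd1 in FLASH against CONV. Total counts gave 0.058 for Scd1 in FLASH against CONV and 0.040 for Cd68 in FLASH against sham, and the replicate block 0.051 for the latter. Limma voom gave 0.51 for Scd1 in FLASH against CONV. With quality weights it gave 0.29 for Fasn, 0.23 for Scd1 and 0.056 for Ccng1 in FLASH against sham, 0.12 for Scd1 and 0.11 for Ccng1 in CONV against sham and 0.11 for Scd1 in FLASH against CONV.

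With 8 libraries edgeR gave 0.10 for Lep, 0.16 for Scd1 and 0.054 for Ccng1 in FLASH against sham, 0.39 for Scd1, 0.00571 for Pparg, 0.19 for Ccng1 and 0.072 for Col3a1 in CONV against sham, and −0.083 for Pparg in FLASH against CONV. DESeq2 gave 0.11, 0.16 and 0.061 for Lep, Scd1 and Ccng1 in FLASH against sham, 0.40, 0.016, 0.20 and 0.086 for Scd1, Pparg, Ccng1 and Col3a1 in CONV against sham, and −0.088 for Pparg in FLASH against CONV. Limma voom gave 0.10, 0.21 and 0.049 for Fasn, Scd1 and Ccng1 in FLASH against sham, 0.40 and 0.20 for Scd1 and Ccng1 in CONV against sham, and −0.041 for Pparg in FLASH against CONV. With quality weights it gave −0.088, 0.34, 0.25 and 0.085 for Lck, Fasn, Scd1 and Ccng1 in FLASH against sham, 0.44 and 0.16 for Scd1 and Ccng1 in CONV against sham, and −0.12 for Pparg in FLASH against CONV. The B cell covariate gave 0.39 and 0.085 for Scd1 and Ccng1 in FLASH against sham, 0.39, 0.14, 0.30, 0.30 and 0.35 for Scd1, Pparg, Ccng1, Col1a1 and Col3a1 in CONV against sham, and −0.15 for Pparg in FLASH against CONV.

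Without the pair some lists turned, with adjusted p of 0.135 for adipocytes, 0.0013 for ribosomal proteins and 0.582 for T and NK cells in FLASH against sham. They were 0.681 for lipolysis and 0.436 for proliferation in CONV against sham, and 0.739, 0.221, 0.163, 0.221 and 0.659 for adipocytes, lipolysis, proliferation, ribosomal proteins and endothelium in irradiated against sham.

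Leaving out each library gave 0 to 1 genes in CONV against sham and 0 to 1 in FLASH against CONV (Socs3 without FLASH replicate 3, Prg4 without CONV replicate 2), 2 to 21, 13 to 23, 8 to 25 and 8 to 21 lists in the 4 comparisons, and an agreement of 0.125 to 0.847. Genes that changed sign ranged, in FLASH against sham, from −0.995 to 0.10 for Lep, −1.02 to 0.34 for Fasn, −0.34 to 0.16 for Scd1, −0.079 to 0.55 for Cdkn1a, −0.25 to 0.054 for Ccng1 and −0.28 to 0.051 for Cd68. In CONV against sham they ranged from −1.45 to 1.64 for Fasn, −0.87 to 0.40 for Scd1, −1.10 to 0.020 for Pparg, −0.22 to 0.20 for Ccng1, −1.21 to 0.083 for Col3a1 and −0.13 to 0.29 for Ccl2. In FLASH against CONV they ranged from −2.53 to 0.40 for Acly, −2.84 to 0.93 for Elovl6, −0.055 to 0.82 for Adipoq, −1.83 to 0.85 for Fasn, −0.55 to 0.73 for Scd1, −0.39 to 0.73 for Pparg, −0.33 to 0.11 for Ccng1, −0.49 to 0.42 for Col1a1 and −0.66 to 0.64 for Col3a1. Lists that turned had adjusted p, in FLASH against sham, from 0.000283 to 0.518 for adipocytes, 7.21e-05 to 0.893 for oxidative phosphorylation, 0.000786 to 0.22 for ribosomal proteins and 0.00107 to 0.876 for T and NK cells. In CONV against sham they had 0.000105 to 0.601 for lipolysis and 2.01e-05 to 0.622 for proliferation. In FLASH against CONV they had 6.98e-06 to 0.607 for adipocytes, 1.16e-08 to 0.910 for lipogenesis, 2.67e-11 to 0.910 for oxidative phosphorylation, 5.38e-06 to 0.0790 for proliferation, 1.93e-06 to 0.118 for ribosomal proteins, 6.69e-05 to 0.211 for B cells and 7.27e-05 to 0.607 for endothelium. The cause of these changes was not tested.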

Other observations

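Without the lymphocyte-rich pair, a set chosen after the data were seen, tests of STAT3 targets and fat mass genes used lists written before their values were seen, and the tests against random lists were chosen only after the result was seen.

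Some other genes stood apart in the CONV libraries without the lymphocyte-rich pair, and they were named after their values were seen and not tested as a group. The cytokine gene Il6 stood at 0.977 ± 0.0229 CPM there (SD, n = 2), against 0.129 ± 0.00661 in sham (n = 3) and 0.0427 ± 0.0157 in FLASH (n = 3), all near the floor in the latter groups. The plasma haemoglobin scavenger Hp stood at 4204 ± 3734 CPM against 817 ± 235 in sham and 1067 ± 76.3 in FLASH, with 1564 in CONV replicate 1 and 6844 in CONV replicate 3, and the transcription factor Cebpd at 22.8 ± 0.163 against 10.2 ± 1.61 and 14.9 ± 0.636. In the lymphocyte-rich CONV replicate 2 Il6 stood at 0.101 CPM, Hp at 134 CPM and Cebpd at 9.65 CPM. The laminin chain Lama3 was low in CONV, at 7.61 ± 1.87 CPM against 30.6 ± 4.37 in sham and 27.3 ± 4.98 in FLASH, with 18.0 in the lymphocyte-rich CONV replicate 2 and 20.5 in FLASH replicate 3.

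The imprinted gene Mest, reported to rise with fat mass gain, stood at 9.17 ± 5.47 CPM in all 3 CONV libraries (range 4.05 to 14.9) against 188 ± 108 in sham (79.8 to 296). In FLASH it ranged from 9.92 CPM in replicate 3 to 433, with 312 ± 140 in the other 3 libraries. Peg3, also imprinted, stood at 52.3 ± 16.1 CPM in CONV, 301 ± 108 in sham and 315 ± 211 in FLASH. Lep stood at 284 ± 175 CPM in CONV, 1493 ± 476 in sham and 1232 ± 1102 in FLASH. These CONV means include lymphocyte-rich CONV replicate 2, whose values cannot be told from lymphoid content. Raw counts in CONV replicates 1 to 3 were 266, 121 and 406 for Mest and 1929, 1004 and 1671 for Peg3. Without the pair Lep stood at 380 ± 80.6 CPM in CONV and 1612 ± 976 in FLASH.

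A hypothesis was that interleukin-6 family cytokines signalled through STAT3 in CONV fat. Without the pair, 12 STAT3-induced genes not looked at before moved up on balance in CONV against sham. Of these, 11 of 12 had a positive fold change, with a median of 0.83, which may point to such signalling. Socs3, itself induced by STAT3, was high in the same 2 CONV libraries. The rise of the 12 genes is thus not independent of that of Socs3. The fry test of limma gave p = 0.00279, and in a permutation of gene membership 1.9% of 1000 random lists of like abundance had as low a p. Bcl3 had 2.15 ± 0.38, Pim1 1.86 ± 0.39, Lrg1 1.63 ± 0.43, Serpina3n 1.49 ± 0.39, Steap4 0.92 ± 0.16 and Stat3 itself 0.72 ± 0.19. Much of the rise of Lrg1, Bcl3, Pim1 and Cebpb lay in CONV replicate 3, with raw counts of 26051, 1208, 1543 and 2826. In CONV replicate 1 they had 8518, 504, 664 and 1122, against at most 7192, 239, 438 and 1349 in sham libraries. Steap4 was close in CONV replicates 1 and 3 (45554 and 51154), and Fgl2, Tifa, Il13ra1 and Il6ra had more counts in CONV replicate 1. The median of the 12 genes lay above all of 10000 random lists of like abundance (100%). The random lists were drawn gene by gene and need not move together as genes of a pathway may. These shares may thus overstate how rare such a result is. In FLASH against CONV, which used the same 2 CONV libraries, the same genes had a median of −0.74, 11 of 12 negative. CONV had 2 libraries in this test, so a difference between samples of another kind is not excluded.

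A second hypothesis was a lower fat mass of the mice in CONV. The 4 genes Sfrp5 (−3.41 ± 0.67), Nnat (−1.12 ± 0.31), Nkd1 (−1.97 ± 0.38) and Stc2 (−0.74 ± 0.33), reported to vary with fat mass gain as Mest does, moved down in CONV against sham without the pair (median −1.54). They were chosen after Mest was seen to be low in these libraries, so their fall is not independent of that of Mest. The fry test of limma gave p = 0.00580, and in a permutation of gene membership 3% of 1000 random lists had as low a p. This is consistent with lower fat mass, but body and fat mass are not given in the sources used here, and again CONV had 2 libraries.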
